A study of Mus musculus with 24 samples.

How the data were processed

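Mononuclear cells of mouse tibialis anterior muscle were profiled by droplet-based 3' single-cell RNA sequencing with version 2 chemistry, per the labels. The mice were wild-type males of 3 to 4 months. Injury was an injection of 50 µl of 1.2% barium chloride, a salt that kills muscle fibres, into the tibialis anterior and the adjoining extensor digitorum longus. Muscles were taken 4 or 7 days later, or were left uninjured. Per the labels' protocols, an injured preparation pooled 2 muscles from 2 mice and an uninjured preparation pooled 6 muscles from 3 mice. Tissue was digested with collagenase at 400 U/mL, dead cells were removed on columns, and red blood cells were depleted with beads against Ter119. The protocol also mentions aged muscle, which was not analysed here.

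The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, in raw matrices that hold every possible barcode (31053 genes). FastQC 0.11.8, Cell Ranger (with no version given in the sources used here) and the mouse build mm10 are named in the submitters' processing notes. Coordinates were taken from the GENCODE annotation of GRCm38, which is the same build, where 31011 of the 31053 gene identifiers were found. The 71 genes that share a symbol with another gene were kept apart by identifier.

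The 24 samples were 4 sublibraries each of 2 replicates in each of the 3 groups, uninjured, day 4 and day 7. The 4 sublibraries of a replicate shared 954 to 998 of their 1000 largest barcodes, and sublibraries of different replicates shared at most 5. Counts of a gene in a barcode differed between sublibraries of a replicate by less than sampling noise, with a median over pairs of the mean chi-square per entry between 0.125 and 0.851, against 1 for independent draws. The pairs with the shallow sublibrary 3 of uninjured replicate 2 were exceptions, at 1.504, 1.552 and 1.575, as were those with the shallow sublibrary 2 of day 4 replicate 1, at 0.9946, 0.9972 and 0.9994. Sublibraries were therefore summed per barcode and each replicate was counted as 1 sample, so n = 2 per group. A molecule can have been counted in up to 4 sublibraries. Where a group held no count of a gene, a fold was taken against a floor of 3 molecules in 4 sublibraries, which is 12 counts over the group. Such floors, and the exact 95% binomial intervals of shares, cover counting error only. Nothing in the labels tells which mice entered which pool, so p-values of cell shares and of single genes measure the spread between 2 pools.

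Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were called cells, which gave 10343. Doublets were marked with the Scrublet method in scanpy at an expected 6%. In 4 of the 6 replicates its automatic threshold marked too few cells, and the top scores up to the expected share were marked instead. The 453 marked cells (4.38%) were left out, and 9890 cells were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 26 clusters. A cluster was called after a cell class only from marker genes listed in advance, with at least 3 of them detected, and 25 clusters received 1 of 12 class names. A class name below therefore means cells like that class. The expected share of a class sum coming from free RNA was estimated from barcodes under 100 UMIs, as the median over marker lists of unrelated classes, which is a rough estimate because single lists differed widely. Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

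Cells are not replicates. The number of cells per class and replicate was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all called cells of a replicate as the library size. UMIs were summed per class and replicate, and classes with at least 20 cells in both replicates of the groups compared were tested with the same edgeR test after TMM scaling. One fit over the groups shared the estimate of the spread. Benjamini-Hochberg adjusted p-values under 0.05 were called changed. Levels are given as CPM, counts scaled to a common total of the class sum, as mean ± SD. Gene lists were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. No call of a list with the preset correlation held with the estimated one. For phagocytic genes in monocytes or macrophages with at least 10 cells at day 4, the estimated correlation, 0.00125, was under the preset. The unadjusted camera p of this list still went from 1.64e-09 to 0.00785. With the estimated correlation camera takes its degrees of freedom from the few replicates, and with the preset one from the number of genes. A lost call is therefore not shown to come from correlation between genes. Camera p-values with the preset correlation do not measure the spread between pools as those of single genes do. The classes, tests, marker genes, gene lists, alternatives and the rule for naming genes were fixed before the data were examined.

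By that rule, each comparison named the 8 genes with the largest rise and the 8 with the largest fall among those past the test. They needed a mean log2 CPM of at least 5 and no overlap between the replicates of the groups. Predicted, mitochondrial, ribosomal protein and haemoglobin genes, markers of another class and genes with over 50% of their UMIs expected from free RNA were left out. The 2 members of each list with the largest change past the test were added, as were Pax7, Myf5, Myod1, Myog, Pdgfra, Col1a1, Postn, Ly6c2, Ccr2, Mrc1, C1qa, Kdr, Pecam1 and Plvap whatever their test. Not all of these are printed.

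Gene tests of monocytes or macrophages against uninjured muscle, of myogenic progenitors and of endothelial cells had been planned and held too few cells. After the data were seen, 3 kinds of test were added. Monocytes or macrophages were tested with at least 10 cells per replicate. Myogenic cells were taken from a clustering of cells with at least 1000 UMIs, with at least 5 cells per replicate and without haemoglobin genes, which had taken 86.6% of the UMIs of these cells in uninjured replicate 2. T or NK cells, tenocytes and dendritic cells were tested as further classes, the last 2 only between day 7 and day 4. These added tests used genes expected at 10 or more counts in the shallowest sum. A difference between classes in their change from day 4 to day 7 was also tested, in 1 fit with an interaction term.

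Simulated counts with 200 changed genes, drawn from the means and depths of the real sums, were put through the same steps. For the tests within a class, the spread of every gene followed its trend, and changed genes had a mean log2 CPM over 5. The shares given for these tests hold for that setting, and genes with their own spread were not simulated there. In fibro-adipogenic progenitors, changes of 1 on the log2 scale were recovered for 78.6%, 85% and 83% of genes in day 4 against uninjured, day 7 against uninjured and day 7 against day 4. Changes of 2 were recovered for 100% in each. False calls made up 4.81%, 6.57% and 3.17% of calls. In monocytes or macrophages between day 7 and day 4 the recovered shares were 72% and 100%, with 2.82% false calls. With at least 10 cells per replicate they were 54.3% and 100% at day 4, and 60.8% and 100% at day 7, against uninjured, with 2.82% and 2.72% false calls. In myogenic cells only 9.52% and 43.8% were recovered, with 0% false calls among 43. With 200 genes changed and 360 tested, unchanged genes were a far smaller share there than in the other fits. This 0% therefore says little about false calls in the real test. In T or NK cells changes of 1 were recovered for 45.8%, 50.9% and 66.7% and changes of 2 for 100%, 98.7% and 100%, with 2.27%, 8.97% and 5.06% false calls. In tenocytes 71.6% and 100% were recovered, with 2.38% false calls, and in dendritic cells 61% and 97%, with 8.67% false calls. For the difference between classes, simulated changes of 2 were recovered for 62.5% with 5.3% false calls when the spread followed its trend. When each gene kept its own spread from a fit without the difference, 43% were recovered with 23.9% false calls. The simulation with the trend was made after the other had been seen.

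Alternatives were the Wald test of DESeq2 1.42.0, its size factors in edgeR, TMM over classes, no filter on low counts or edgeR's own, the replicate number as a block, leaving out each replicate, at least 1000 UMIs per cell, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, and the highest sublibrary count in place of the sum. Others left out the 2 sublibraries with far fewer UMIs than the others of their replicate, genes mostly from free RNA, or a mixed cluster of low UMIs, thinned the sums to equal totals, or took shares among non-immune classes only.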

Results

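Single mononuclear cells were sequenced from uninjured mouse tibialis anterior muscle and from muscle 4 and 7 days after injury with barium chloride, to follow the cells present as the muscle regenerated. Each group had 2 replicate pools. The deposited counts summed to 7300417 and 5993060 UMIs in the uninjured replicates, 30548432 and 68160830 at day 4, and 23029715 and 28276410 at day 7. After filtering, 747 and 612 uninjured cells, 2741 and 2756 day 4 cells, and 788 and 2246 day 7 cells were kept. Their median UMI numbers were 5830 and 6439, 8435 and 17949, and 14617.5 and 7165.5, so uninjured muscle was the least deeply sampled. The 4 sublibraries deposited for each replicate shared their barcodes and were counted as 1 sample. Between sublibraries, counts differed by less than the sampling noise, except in the pairs with the shallow sublibrary 3 of uninjured replicate 2 (mean chi-square 1.504 to 1.575, against 1 for independent draws) and in those with the shallow sublibrary 2 of day 4 replicate 1 (0.9946 to 0.9994). Cells were named from marker genes into 12 classes, among them fibro-adipogenic progenitors (FAPs), the mesenchymal fibroblast-like cells of muscle, and immune, endothelial, glial and muscle cells.

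Of the mononuclear cells recovered, FAPs and endothelial cells were the largest classes in uninjured muscle, and monocytes or macrophages were the largest at day 4. All shares are of recovered cells and not of the tissue. Uninjured and injured preparations pooled different numbers of muscles and mice, and a difference in yield between them was not tested. Monocytes or macrophages rose from 2.39% ± 0.544 (SD, n = 2) of cells to 44.0% ± 2.45, a log2 change of 4.2 ± 0.51 (SE; edgeR adjusted p = 0.000791). Dendritic cells rose from 0.609% ± 0.294 to 12.3% ± 3.08 (log2 change 4.34 ± 0.61, adjusted p = 0.0013). Endothelial cells, which line blood vessels, fell from 10.8% ± 3.99 to 0.0909% ± 0.0254 (log2 change -6.78 ± 1.05, adjusted p = 0.00166), and cells with mature myofiber transcripts fell from 4.78% ± 2.14 to 0.0364% (2 of 5497 cells; log2 change -6.77 ± 0.82, adjusted p = 0.000791). Schwann or glial cells, the support cells of nerves, were 48 of 747 and 8 of 612 cells in the uninjured replicates (3.87% ± 3.62) and 0 of 5497 at day 4 (adjusted p = 0.0092). Cells named differentiating myocytes were 174 of 5497 at day 4 against 0 of 1359, which allows up to 0.221% (adjusted p = 0.0092). These day 4 cells were mixed: 34.5% had a UMI of Pax7, 40.8% of Myog and 64.9% of Top2a. The 28 uninjured myogenic cells lay in another cluster, named myogenic progenitor. This call ended with at least 1000 UMIs per cell, where myogenic cells shared 1 cluster.

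FAPs fell as a share of all cells at day 4, from 64.4% ± 6.24 to 28.3% ± 2.62 (log2 change -1.19 ± 0.42, edgeR adjusted p = 0.0418), and B cells fell from 2.21% ± 1.04 to 0.673% ± 0.183 (log2 change -1.69 ± 0.59, adjusted p = 0.0418). T or NK cells, at 4.99% ± 0.805 and 4.73% ± 2.59, did not pass the test (log2 change -0.07 ± 0.55, adjusted p = 0.9), nor did neutrophils, tenocytes and the cluster named myogenic progenitor. Counting 1 cluster that received no name, 9 of the 13 groups of cells changed. Among non-immune classes alone the share of FAPs moved the other way (log2 change 0.20, not past the test) and 4 classes changed. The FAP call ended without uninjured replicate 1 (-1.28), uninjured replicate 2 (-1.08), day 4 replicate 1 (-1.09) or day 4 replicate 2 (-1.28), and with TMM over classes (-1.26) or Leiden resolution 2 (-1.19). The B cell call ended without uninjured replicate 2 (-1.12) or either day 4 replicate (-1.99 and -1.44) and with TMM over classes (-1.75), and the call of differentiating myocytes ended with at least 1000 UMIs per cell (0.67) or without low sublibraries (0.74). Both calls, and that of Schwann or glial cells, also ended with the replicate number as a block.

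At day 7 T or NK cells were the largest class, and monocytes or macrophages made up a smaller share of recovered cells than at day 4. T or NK cells made up 45.0% ± 5.00 (SD, n = 2) of cells, above uninjured muscle (log2 change 3.18 ± 0.59 SE, edgeR adjusted p = 0.0127) and above day 4 (3.25 ± 0.58, adjusted p = 0.00388). Monocytes or macrophages were down to 7.51% ± 0.863, below day 4 (log2 change -2.55 ± 0.46, adjusted p = 0.00388) and still above uninjured muscle (1.65 ± 0.48, adjusted p = 0.0261). Dendritic cells, at 3.83% ± 0.321, likewise lay below day 4 (-1.68 ± 0.50, adjusted p = 0.0343) and above uninjured muscle (2.66 ± 0.61, adjusted p = 0.0157). Cells with myofiber transcripts were back at 4.03% ± 1.66 (day 7 against day 4, log2 change 6.50 ± 0.81, adjusted p = 0.00195), and their difference from uninjured muscle was not past the test (-0.28, adjusted p = 0.638). Endothelial cells stayed below uninjured muscle at 0.312% ± 0.441 (log2 change -4.75 ± 0.94, adjusted p = 0.0127), and Schwann or glial cells were 0 of 3034. Neither of these 2 classes passed the test against uninjured muscle with the replicate number as a block.

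FAPs made up 25% ± 2.19 of day 7 cells, below uninjured muscle (log2 change -1.36 ± 0.43, edgeR adjusted p = 0.0261) and not different from day 4 past the test (-0.18 ± 0.42, adjusted p = 0.744). Differentiating myocytes were 43 of 3034 cells (adjusted p = 0.0261 against uninjured), a call that ended without uninjured replicate 1 or day 7 replicate 2 and turned with at least 1000 UMIs per cell (-0.54). The cluster named myogenic progenitor fell from 2.01% ± 0.759 to 0.397% ± 0.383 (log2 change -2.10 ± 0.74, adjusted p = 0.0354), and this call ended without uninjured replicate 1 (-1.64), day 7 replicate 1 (-1.59) or either day 4 replicate (-2.12), and with TMM over classes (-2) or Leiden resolution 2 (-2.14). It is a change of that cluster and not of all progenitor-like cells, because of the 43 day 7 cells named differentiating myocytes 16.3% had a UMI of Pax7 and 27.9% of Chodl. In the clustering with at least 1000 UMIs, where myogenic cells shared 1 cluster, they were 19 of 747 and 9 of 612 uninjured cells and 4 of 788 and 47 of 2243 day 7 cells. Tenocytes, the fibroblasts of tendon, rose to 8.32% ± 4.21 from 0.928% ± 0.0808 at day 4 (log2 change 3.14 ± 0.57, adjusted p = 0.00388), a call that ended with at least 1000 UMIs per cell (0.79) or without low sublibraries (0.19). The clusters that carried this name depended on the clustering, and against uninjured muscle their direction turned with at least 1000 UMIs per cell (-3.70), doublets kept (-1.24), Leiden resolution 2 (-1.17) or without low sublibraries (-4.38). In all, 10 groups of cells changed against uninjured muscle and 5 against day 4. These counts dropped to 3 without uninjured replicate 1 and to 6 without day 7 replicate 1 in the former, and to 1 without day 4 replicate 2 in the latter. In that fit the changes of T or NK cells (2.78), monocytes or macrophages (-2.49) and tenocytes (3.05) missed the threshold, and myofiber transcripts were the 1 class left.

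Several of the day 7 calls were close to the threshold. Against uninjured muscle the change in FAPs missed it without any 1 of the 6 replicates (log2 change -1.46 to -1.26) and with TMM over classes (-1.25). That of monocytes or macrophages missed it without uninjured replicate 1 (1.43), day 7 replicate 1 (1.53) or either day 4 replicate (1.65) and with TMM over classes (1.76). Dendritic cells missed it without uninjured replicate 1 (2.22), and tenocytes did without uninjured replicate 1 (2.48). The change in dendritic cells between day 7 and day 4 missed it without any 1 of the day 4 or day 7 replicates (-1.92 to -1.40), with TMM over classes (-1.53) or with at least 1000 UMIs per cell (-1.16). Among non-immune classes alone, 4 classes changed against uninjured muscle and 2 against day 4.

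**Figure D1:**
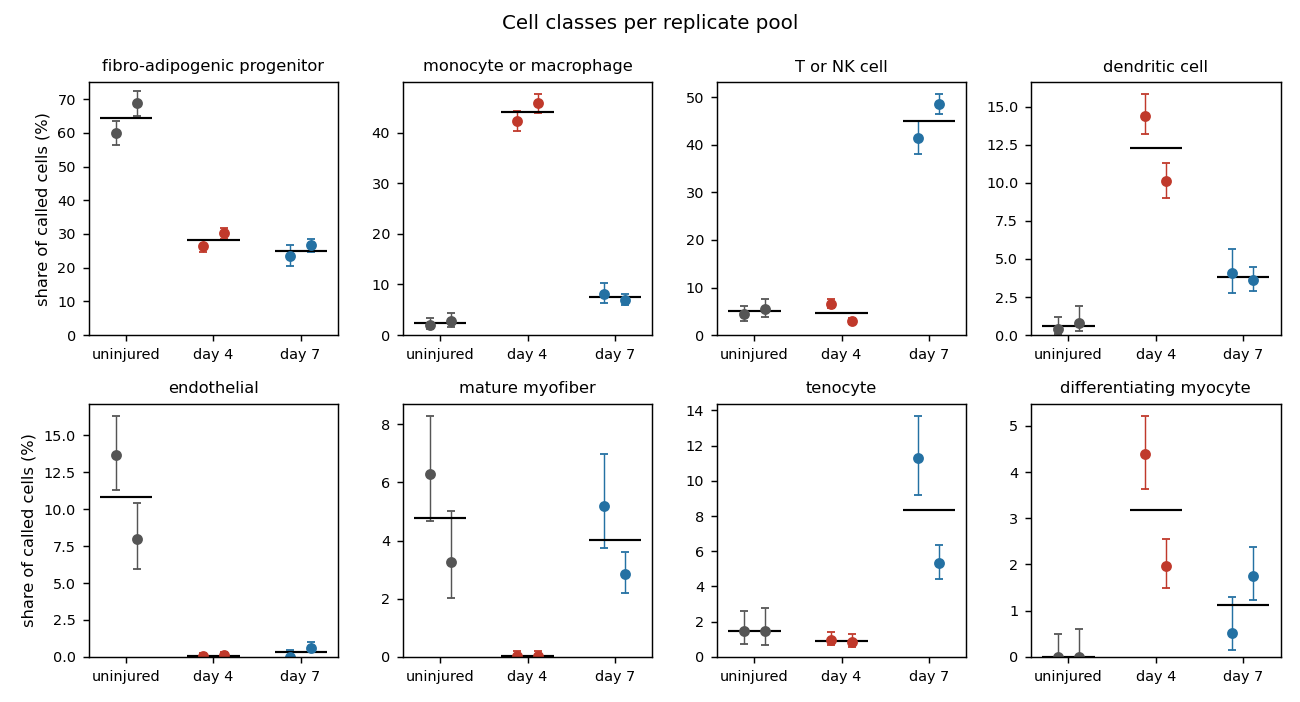
Share of called cells (percent, vertical axis, with a separate scale in each panel) in 8 cell classes for uninjured muscle and for days 4 and 7 after injury. Points are the 2 replicate pools of a group with exact 95% binomial intervals, and lines are group means; monocytes or macrophages have a mean of 44.0% at day 4 and T or NK cells of 45.0% at day 7.

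In FAPs 4 days after injury, genes of cell division, interferon signalling, energy metabolism and much of the extracellular matrix were higher than in uninjured muscle, and genes of the resting fibroblast were far lower. The list tests behind this passed with the preset correlation and not with an estimated one (adjusted p = 0.144 to 0.403). Hp, which encodes the haemoglobin-binding plasma protein haptoglobin, had no count in uninjured FAPs and rose to 148 ± 9.67 CPM (SD, n = 2), at least 75.5-fold (adjusted p = 2.41e-06). The matrix genes Tnc (tenascin C, at least 59.8-fold, adjusted p = 3.1e-05) and Postn (periostin, from 12 ± 7.69 to 993 ± 176 CPM, 83-fold, adjusted p = 5.66e-06; log2 change 7.27 in place of 6.38 without uninjured replicate 1) rose, as did Il1rl1, the receptor of the alarm cytokine interleukin 33 (at least 36.4-fold, adjusted p = 5.91e-05). Gsn, which encodes the actin-severing protein gelsolin, fell 49.3-fold from 35370 ± 2114 to 717 ± 87.4 CPM (log2 change -5.62 ± 0.19, adjusted p = 1.06e-06). Inmt, an N-methyltransferase, fell 425-fold and Bmp4, a growth factor of the bone morphogenetic protein family, fell 26.6-fold (adjusted p = 2.41e-06 and 4.76e-06). In mm10, Hp (ENSMUSG00000031722) lies on chromosome 8 at 109575128-109579172, Tnc (ENSMUSG00000028364) on chromosome 4 at 63959785-64047015, Postn (ENSMUSG00000027750) on chromosome 3 at 54361109-54391037 and Gsn (ENSMUSG00000026879) on chromosome 2 at 35256380-35307892.

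Over all genes, 4886 of 12232 changed in FAPs at day 4 (2624 higher, 2262 lower, edgeR), or 2029 higher and 2061 lower with the highest sublibrary count. The count was 2868 without day 4 replicate 1 and 2937 without day 4 replicate 2. FAPs of the 2 groups lay in different clusters, 81.6% of uninjured ones in cluster 5 and 54.8% of day 4 ones in cluster 3. The estimated share of their UMIs from free RNA was 5.87% and 9.94% in the uninjured replicates and 28.0% and 28.8% at day 4.

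Of 22 cell cycle genes, 21 rose and 1, Pcna, fell at day 4, with a median log2 change of 3.82 (camera adjusted p = 4.05e-07; adjusted p = 0.344 with an estimated correlation). Ccnb1, a mitotic cyclin, had no count in uninjured FAPs and reached 33.8 ± 3.80 CPM (at least 17.2-fold), of which 42.4% was expected from free RNA. Of 16 interferon response genes 15 rose and none fell (median 2.36, adjusted p = 3.61e-07; adjusted p = 0.144 with an estimated correlation), among them Ifi44 (at least 11.7-fold). Of 24 matrix genes 17 rose and 3 fell (median 1.08, adjusted p = 4.98e-05; adjusted p = 0.144 with an estimated correlation). Those that fell were Col6a1 and Col6a2, chains of the pericellular collagen VI, and the gelatinase Mmp2, while Col1a1, the main chain of collagen I, rose 2.14-fold (adjusted p = 8.96e-05; the call ended with the highest sublibrary count). Of 12 steady-state fibroblast genes 11 fell and 1, Ly6a, rose (median -3.03, adjusted p = 7.62e-06; adjusted p = 0.144 with an estimated correlation). Hsd11b1, which activates glucocorticoids, fell 20.8-fold. Of 16 immediate early and dissociation response genes 15 fell and 1, Ier3, rose (median -1.49, adjusted p = 3.24e-06; adjusted p = 0.195 with an estimated correlation), and the near-identical heat shock genes Hspa1a and Hspa1b, whose reads cannot be fully told apart, fell 10.2-fold and 14.3-fold.

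Of 22 oxidative phosphorylation genes 15 rose and 1 fell (adjusted p = 0.000491; adjusted p = 0.144 with an estimated correlation). Of 15 glycolysis genes 11 rose and 2 fell (adjusted p = 0.00384; adjusted p = 0.403 with an estimated correlation), with Pgk1, a glycolytic kinase, up 8.88-fold. Of 14 ribosome biogenesis genes 8 rose and 1 fell (adjusted p = 0.0366; adjusted p = 0.403 with an estimated correlation), a list call that ended without uninjured replicate 1 (adjusted p = 0.0597) or 2 (adjusted p = 0.0939). The lists of p53 targets (2 of 12 rose, 1 fell) and of growth factors and niche ligands (6 of 20 rose, 5 fell) did not move together (adjusted p = 0.327 and 0.434). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, fell 2.88-fold, and Pdgfra, the receptor that marks FAPs, fell 2.75-fold from 246 ± 18.5 to 89.6 ± 1.04 CPM (adjusted p = 0.000181). Adjusted over the list alone, 16 oxidative phosphorylation genes and 7 growth factors rose, and the other counts were the same.

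By day 7 the matrix genes of FAPs stood higher still, while the resting fibroblast genes remained low. These list calls did not hold with an estimated correlation (adjusted p = 0.116 and 0.243). Postn was at 4130 ± 451 CPM (SD, n = 2), 345-fold above uninjured muscle (adjusted p = 3.51e-06), and Col1a1 rose 6.06-fold to 9405 ± 127 CPM (log2 change 2.60 ± 0.11 SE, adjusted p = 3.51e-06). Tnc (at least 145-fold) and the acute-phase gene Saa3, which has close homologues (at least 132-fold), rose from no count. H19, an imprinted non-coding RNA of fetal tissue, rose 312-fold to 2403 ± 37.9 CPM (adjusted p = 9.89e-05). Gsn fell 37.1-fold, Inmt 253-fold, Hsd11b1 86.8-fold and Bmp4 23.7-fold, with adjusted p of 3.1e-05 or less. Without 1 replicate some of these log2 changes moved, as far as 9.33 for Postn (without uninjured replicate 1), and -9.37 for Inmt and -7.41 for Hsd11b1 (without day 7 replicate 2). That of H19 was 7.31 without uninjured replicate 2. It was 17.7 without uninjured replicate 1, which held its only uninjured counts, so its fold rests on that replicate. Over all genes, 3432 of 12232 changed (1997 higher, 1435 lower, edgeR), or 1284 higher and 1290 lower with the highest sublibrary count, and 2256 did without day 7 replicate 1. Day 7 FAPs lay mostly in cluster 7 (74.8%), with 13.5% and 19.6% of their UMIs expected from free RNA.

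Of the 24 matrix genes 20 rose and none fell at day 7 against uninjured muscle (median log2 change 1.92, camera adjusted p = 1.37e-10; adjusted p = 0.116 with an estimated correlation). Interferon response genes rose for 15 of 16 (adjusted p = 1.52e-07; adjusted p = 0.243 with an estimated correlation) and cell cycle genes for 19 of 22, with 1 falling (adjusted p = 8.22e-06; adjusted p = 0.422 with an estimated correlation). Immediate early genes fell for 12 of 16, with 1 rising (adjusted p = 7.19e-05; adjusted p = 0.337 with an estimated correlation), and steady-state fibroblast genes fell for 9 of 12, with 1 rising (adjusted p = 8.18e-05; adjusted p = 0.243 with an estimated correlation). Glycolysis genes rose for 10 of 15, with 2 falling (adjusted p = 0.0291; adjusted p = 0.582 with an estimated correlation), a call that ended without uninjured replicate 1 (adjusted p = 0.12) or 2 (adjusted p = 0.0686). The lists of oxidative phosphorylation (7 of 22 rose), ribosome biogenesis (2 of 14 rose, 1 fell), p53 targets (1 of 12 rose, 1 fell) and growth factors (4 of 20 rose, 5 fell) did not pass (adjusted p = 0.0919, 0.898, 0.536 and 0.463). Adjusted over the list alone, 1 more cell cycle, oxidative phosphorylation, glycolysis and growth factor gene rose, and 1 more immediate early and growth factor gene fell.

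Between day 4 and day 7, matrix genes rose in FAPs, and among single genes Cdkn1c and Dlk1 rose. The call of the matrix list did not hold with an estimated correlation (adjusted p = 0.155). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 35.1-fold from 10.7 ± 2.53 to 380 ± 85.8 CPM (log2 change 5.13 ± 0.24, adjusted p = 1.93e-05). Dlk1, a gene for a membrane protein that restrains fat cell formation, rose 16.7-fold to 344 ± 22.1 CPM (adjusted p = 1.93e-05), and Plagl1, a zinc finger gene, rose 9.36-fold (adjusted p = 0.000178). C1qtnf3, which encodes a secreted protein of the C1q and tumour necrosis factor family, rose 28.5-fold. Wisp2, a gene of the CCN family of matrix-associated proteins, fell 6.23-fold from 444 ± 3.16 to 71.4 ± 7.13 CPM (adjusted p = 5.21e-05). The chemokine genes Cxcl5 and Cxcl12 fell 3.98-fold and 2.51-fold (adjusted p = 0.00206 and 0.000916), and Igf1, a growth factor for muscle, rose 2.93-fold (adjusted p = 0.00934; the call ended with doublets kept). In mm10, Cdkn1c (ENSMUSG00000037664) lies on chromosome 7 at 143458339-143461050, Dlk1 (ENSMUSG00000040856) on chromosome 12 at 109452823-109463336 and Col1a1 (ENSMUSG00000001506) on chromosome 11 at 94936224-94953042.

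In this comparison 709 of 12232 FAP genes changed (425 higher, 284 lower, edgeR). The count was 154 without day 7 replicate 2, 208 without day 4 replicate 1, 317 without day 4 replicate 2 and 446 with doublets kept. It was 1090 with DESeq2 (529 higher, 561 lower) and 1571 without a filter on low counts (774 higher, 797 lower), so the excess of higher genes was not kept. Of 24 matrix genes 15 rose and 1, Timp1, an inhibitor of matrix metalloproteinases, fell (median 0.83, camera adjusted p = 1.14e-08; adjusted p = 0.155 with an estimated correlation). Postn rose 4.16-fold and Col1a1 2.84-fold. Steady-state fibroblast genes rose for 4 of 12, among them Clec3b, which encodes tetranectin (4.24-fold), and fell for 1 (adjusted p = 0.00307; adjusted p = 0.278 with an estimated correlation). Immediate early genes rose for 4 of 16 (adjusted p = 0.000452; adjusted p = 0.285 with an estimated correlation), with Atf3 up 2.91-fold and Dusp1 up 2.54-fold. Pdgfra did not pass the test (log2 change -0.15 ± 0.16, adjusted p = 0.636).

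The cell cycle list was lower at day 7 than at day 4 (median -1.06, adjusted p = 3.96e-05; adjusted p = 0.374 with an estimated correlation), although 1 of the 22, Cdc20, passed the test on its own, a call that ended without day 4 replicate 1 or 2, day 7 replicate 2 or uninjured replicate 2. Lower lists were oxidative phosphorylation (2 of 22 fell, adjusted p = 5.28e-05; adjusted p = 0.181 with an estimated correlation), ribosome biogenesis (3 of 14 fell, adjusted p = 5.28e-05; adjusted p = 0.259 with an estimated correlation) and glycolysis (1 of 15 fell, adjusted p = 0.00282; adjusted p = 0.374 with an estimated correlation). The list of growth factors (4 of 20 fell, 1 rose, adjusted p = 0.00211; adjusted p = 0.259 with an estimated correlation) and the steady-state list missed the threshold without day 7 replicate 2 (adjusted p = 0.0939 and 0.065). The interferon list (1 of 16 fell, adjusted p = 0.0473; adjusted p = 0.388 with an estimated correlation) missed it without day 4 replicate 1 (adjusted p = 0.333), either day 7 replicate or either uninjured replicate (adjusted p = 0.057 to 0.101). None of the 12 p53 targets changed (adjusted p = 0.369). Adjusted over the list alone, the matrix list had 17 rising, the immediate early list 11 rising and 1 falling, and the steady-state list 8 rising. The cell cycle, oxidative phosphorylation, glycolysis, ribosome biogenesis and growth factor lists then had 3, 8, 6, 8 and 6 members falling.

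**Figure D2:**
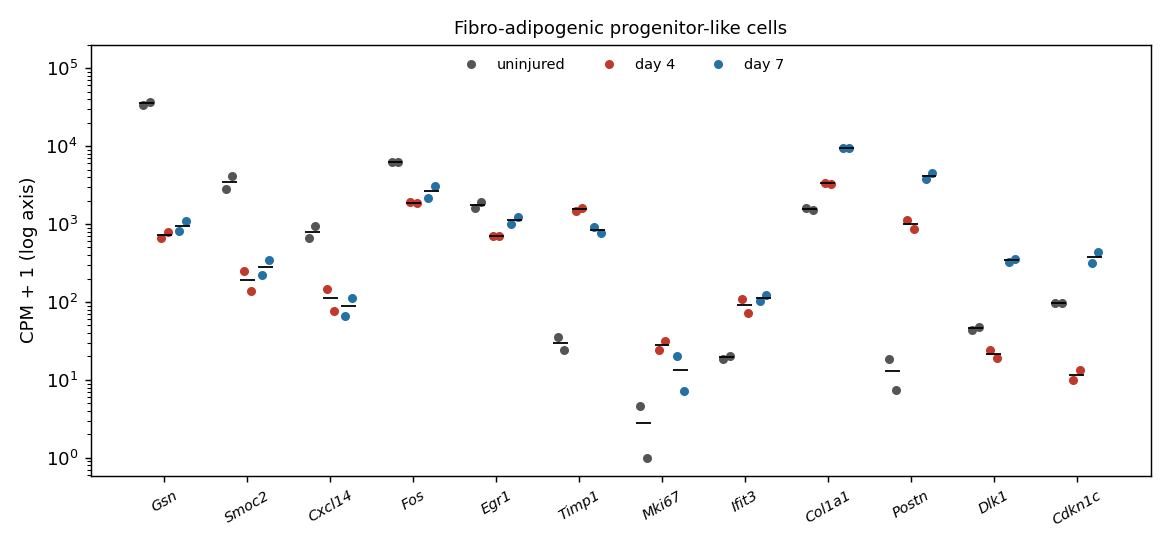
Expression of 12 genes in fibro-adipogenic progenitors of uninjured muscle and at days 4 and 7 after injury, as CPM of the class sum plus 1 on a log axis. Points are the 2 replicate pools of a group and lines are group means; Gsn falls from a mean of 35370 to 717 at day 4, and Col1a1 reaches 9405 at day 7.

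Monocytes or macrophages at day 7 carried more antigen presentation and monocyte genes, and fewer phagocytic and division genes, than at day 4. The list tests behind this did not pass with an estimated correlation (adjusted p = 0.408 to 0.437). H2-Eb1 and H2-Ab1, which encode chains of the MHC class II molecules that present antigen and belong to a family of similar genes, rose 4.44-fold and 4.04-fold to 5277 ± 1854 and 7835 ± 2757 CPM (adjusted p = 0.0367 and 0.0366). Ccr2, the chemokine receptor of recruited monocytes, rose 2.73-fold from 109 ± 2.97 to 298 ± 2.68 CPM (adjusted p = 0.00699). Il1rn, the natural antagonist of interleukin 1, rose 6.4-fold (adjusted p = 0.00865) and complement C3 rose 6.27-fold (adjusted p = 0.00287). Spp1, which encodes osteopontin, fell 6.31-fold from 6504 ± 1841 to 1033 ± 562 CPM (adjusted p = 0.0175), Fabp5, a fatty acid binding protein, fell 5.3-fold (adjusted p = 0.00109) and Syngr1 fell 13-fold (adjusted p = 0.00101). Ly6c2, which resembles its neighbour Ly6c1 (adjusted p = 0.0696), the mannose receptor gene Mrc1 (0.23) and the complement gene C1qa (0.398) did not pass the test. Ly6c2 passed without day 4 replicate 1, day 4 replicate 2 or day 7 replicate 1 and Mrc1 passed without day 7 replicate 2. Spp1 (ENSMUSG00000029304) lies on chromosome 5 at 104435118-104441050.

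Of 9738 genes, 402 changed (249 higher, 153 lower, edgeR). The count was 239 with at least 1000 UMIs per cell, 626 with the highest sublibrary count, 680 with DESeq2 and 1087 without day 7 replicate 1. More genes were lower than higher without day 7 replicate 2 (1549, of which 689 higher and 860 lower) and without a filter (1223, of which 546 higher and 677 lower). The log2 changes of H2-Eb1 and H2-Ab1 were 2.97 and 2.75 without day 4 replicate 1, and that of Spp1 was -3.37 without day 7 replicate 1. With at least 1000 UMIs per cell the calls of H2-Eb1 and H2-Ab1 ended. Clusters 0 and 2 held 41.4% and 33.9% of these cells at day 4, and clusters 6 and 2 held 44.3% and 42.5% at day 7. Changes between the days can therefore also lie in the make-up of the class.

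All 6 changed members of the 8 genes of antigen presentation by MHC class II rose (median 1.80, camera adjusted p = 7.68e-06; adjusted p = 0.437 with an estimated correlation). Ly6c-high monocyte genes rose for 4 of 10 (adjusted p = 1.16e-05; adjusted p = 0.437 with an estimated correlation) and immediate early genes for 3 of 15 (adjusted p = 0.000194; adjusted p = 0.576 with an estimated correlation). Of 17 phagocytic and repair macrophage genes 11 fell (median -1.09, adjusted p = 2.57e-06; adjusted p = 0.408 with an estimated correlation), and of 22 cell cycle genes 9 fell (median -2.32, adjusted p = 2.57e-06; adjusted p = 0.437 with an estimated correlation), among them Birc5, which encodes the division protein survivin (6.31-fold, or a log2 change of -3.75 without day 7 replicate 2). The inflammatory cytokine list (2 of 13 rose, adjusted p = 0.0768) passed only without day 4 replicate 1 (adjusted p = 0.0497). The lists of extracellular matrix (0 of 20 changed), oxidative phosphorylation (0 of 22), glycolysis (2 of 14 rose), ribosome biogenesis (0 of 13), interferon response (1 of 16 rose), p53 targets (0 of 10) and resident macrophages (1 of 10 rose, 4 fell) did not pass, with adjusted p from 0.0983 for interferon response to 0.831 for p53 targets. Adjusted over the list alone, 7 MHC class II, 8 Ly6c-high monocyte and 8 immediate early genes rose, and 13 phagocytic and 17 cell cycle genes fell.

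Against uninjured muscle, phagocytic genes rose in monocytes or macrophages, a list call that did not hold with an estimated correlation (adjusted p = 0.0942 and 0.102). The class had only 15 and 17 uninjured cells. Of these 84.4% lay in cluster 6, against 21.6% at day 4 and 44.3% at day 7. None lay in cluster 0, which held 41.4% at day 4. The changes of genes and lists in this class against uninjured muscle can therefore lie in its make-up. Gpnmb, a glycoprotein gene of phagocytic macrophages, had no count in uninjured cells and stood at 1633 ± 17.0 CPM (SD, n = 2) at day 4, at least 43.2-fold higher (adjusted p = 0.000741), and at 329 ± 78.4 CPM at day 7 (at least 8.7-fold, adjusted p = 0.00741). Ms4a7, which encodes a membrane protein of macrophages, rose at least 38.2-fold and 28-fold. Retnla, a secreted protein of alternatively activated macrophages, fell from 4945 ± 91.3 to 0.740 ± 0.0599 CPM at day 4, a drop of 6360-fold (adjusted p = 2.13e-05), and to no count at day 7 (at least 891-fold, adjusted p = 5.07e-05). Ccr2 fell 3.09-fold at day 4 (adjusted p = 0.00811) and C1qa rose 5.48-fold (adjusted p = 0.0111), calls that ended without either day 4 replicate, while Ly6c2 did not pass (adjusted p = 0.12). At day 7 Ccr2 and Ly6c2 did not pass (adjusted p = 0.595 and 0.517), and C1qa rose 6.43-fold (adjusted p = 0.0242), a call that ended without any of the 4 injured replicates. The log2 change of C1qa was 1.91 and 3.41 at day 4, and 2.13 and 3.63 at day 7, without uninjured replicate 1 or 2. Mrc1 had no count in uninjured cells and 66.5 ± 1.48 CPM at day 4, under the depth that these tests required. The calls at day 7 of Gpnmb and Ms4a7 ended without either day 7 replicate. Retnla (ENSMUSG00000061100) lies on chromosome 16 at 48842551-48844461 and Gpnmb (ENSMUSG00000029816) on chromosome 6 at 49036546-49070929.

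Of 1836 genes deep enough to test, 563 changed at day 4 (283 higher, 280 lower) and 215 at day 7 (132 higher, 83 lower, edgeR). The day 4 count was 107 and 118 without day 4 replicate 1 or 2, 369 without day 7 replicate 1, 289 with the highest sublibrary count and 355 with thinned sums. It was 857 with edgeR's own filter (622 higher, 235 lower) and 1504 without one (1122 higher, 382 lower). The day 7 count was 4 without day 7 replicate 1 or 2, 39 and 36 without day 4 replicate 1 or 2, 440 and 406 without uninjured replicate 1 or 2, 497 with DESeq2, 315 with edgeR's own filter (288 higher, 27 lower) and 853 without one (722 higher, 131 lower). The balance of higher and lower genes therefore depended on which genes were deep enough to test.

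Of 13 phagocytic and repair genes deep enough, 11 rose at day 4 (median log2 change 3.52, or 3.18 with genes at 0 set to their bound; adjusted p = 1.97e-08; adjusted p = 0.0942 with an estimated correlation) and 10 at day 7 (adjusted p = 5.57e-08; adjusted p = 0.102 with an estimated correlation). Of 9 Ly6c-high monocyte genes 8 fell at day 4 (median -2.15, adjusted p = 3.03e-05; adjusted p = 0.226 with an estimated correlation) and 2 at day 7 (adjusted p = 0.00403; adjusted p = 0.312 with an estimated correlation). Folr2 and Selenop, 2 of the 3 resident macrophage genes tested, rose at both times (adjusted p = 0.0257 and 0.0274 for the list; adjusted p = 0.282 and 0.312 with an estimated correlation). MHC class II genes passed at day 7, with 4 of 6 rising (adjusted p = 0.00923; adjusted p = 0.438 with an estimated correlation), and not at day 4, with none of 6 changed (adjusted p = 0.407). Inflammatory cytokine genes passed at day 7, with 3 of 9 rising (adjusted p = 0.0387; adjusted p = 0.438 with an estimated correlation), and not at day 4, with 2 rising and 1 falling (adjusted p = 0.371). Compared directly between day 7 and day 4, without uninjured cells, the MHC class II list rose (camera adjusted p = 7.68e-06, or 0.437 with an estimated correlation). The cytokine list did not pass there (camera adjusted p = 0.0768). Adjusted over the list alone, 13 and 11 phagocytic genes rose at days 4 and 7, 8 and 7 Ly6c-high monocyte genes fell, and 0 and 6 MHC class II genes rose. At day 7 the calls ended without uninjured replicate 1 for MHC class II (adjusted p = 0.142), and without uninjured replicate 2 for cytokines (0.482), Ly6c-high monocyte genes (0.0684) and resident macrophage genes (0.105). The cytokine call also ended without day 7 replicate 2 (0.0923). The call of Selenop ended without any 1 replicate of the group tested.

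Lists that did not pass in these cells were cell cycle (1 of 4 fell at both times, adjusted p = 0.431 at day 4 and 0.22 at day 7), immediate early genes (0.312 and 0.664), oxidative phosphorylation (0.218 and 0.621), glycolysis (0.254 and 0.22), ribosome biogenesis (0.453 and 0.606), interferon response (0.371 and 0.0536) and p53 targets (0.218 and 0.119). The interferon list at day 7 passed without uninjured replicate 2, either day 4 replicate or day 7 replicate 1 (adjusted p = 0.0235 to 0.0459). At day 4 the cytokine list passed without uninjured replicate 1 (0.025) and the MHC class II list without day 4 replicate 1 (0.0405), and at day 7 the cell cycle list without uninjured replicate 2 (0.0466). At day 4, 4 of 9 glycolysis genes rose and 2 fell, and 6 of 21 oxidative phosphorylation genes rose and 1 fell.

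Many myogenic cells at day 4 had UMIs of genes of committed muscle precursors and of Top2a, and Chodl was lower than in the uninjured ones. In the clustering with at least 1000 UMIs used here they shared 1 cluster. The clustering behind the shares put 28 uninjured cells in cluster 20, named myogenic progenitor, and 174 day 4 cells in cluster 12, named differentiating myocyte. Of the 174 day 4 cells, 34.5% had a UMI of Pax7, the transcription factor of satellite cells, 62.1% of Myod1 and 40.8% of Myog, which drive commitment and differentiation, and 64.9% of Top2a, a gene of dividing cells. The shares in T or NK cells, which should lack the muscle genes, were 0% for Pax7, 0.385% for Myod1 and Myog and 10.4% for Top2a, at a median of 3167 UMIs against 28695. Of the 28 uninjured cells, at a median of 3996 UMIs, 57.1% had a UMI of Chodl, a gene of quiescent satellite cells, 35.7% of Myod1 and 10.7% of Pax7, against 0% of 67 T or NK cells at a median of 4894 UMIs. Myog was at 415 ± 79.7 CPM at day 4 (SD, n = 2) and had no count in uninjured cells, Myod1 was at 160 ± 17.8 and 245 ± 99.1, Myf5 at 20.5 ± 0.533 and 120 ± 45.7, and Pax7 at 24.4 ± 6.53 and 59.8 ± 84.5 CPM. These 4 genes were not deep enough to test.

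Lgals1, which encodes galectin 1, rose 21.5-fold from 956 ± 37.6 to 20650 ± 622 CPM in day 4 myogenic cells (log2 change 4.43 ± 0.08 SE, adjusted p = 0.0017), and Gpx3, a secreted glutathione peroxidase, fell 93.8-fold (adjusted p = 0.0141). Both calls held without either day 4 replicate, with a log2 change of Gpx3 of -7.56 or -5.93 without day 4 replicate 1 or 2. Chodl was at 1655 ± 551 CPM in uninjured and 0.432 ± 0.610 in day 4 cells (adjusted p = 0.00866), and Nppc, which encodes C-type natriuretic peptide, fell at least 404-fold to no count (adjusted p = 0.0088), calls that ended without either day 4 replicate. Of 423 genes 186 changed (91 higher, 95 lower, edgeR), and 5 did without day 4 replicate 1 or without day 4 replicate 2, 651 without uninjured replicate 2, 110 with thinned sums, 1309 with edgeR's own filter (1044 higher, 265 lower) and 854 without one (681 higher, 173 lower). Immediate early genes fell for 8 of 8 (adjusted p = 0.000602; adjusted p = 0.202 with an estimated correlation), glycolysis genes rose for 7 of 7 (adjusted p = 0.00191; adjusted p = 0.202 with an estimated correlation) and oxidative phosphorylation genes for 6 of 14, or 12 adjusted over the list alone (adjusted p = 0.0047; adjusted p = 0.202 with an estimated correlation). Of 11 RNA-binding and splicing genes deep enough, Zfp36 and Srsf5 fell (adjusted p = 0.197 for the list), and ribosome biogenesis (2 of 5 rose, 1 fell) and cell cycle genes (2 of 3 rose) did not pass (adjusted p = 0.335 and 0.227). Without uninjured replicate 2 the RNA-binding and cell cycle lists passed (adjusted p = 0.0424 and 0.00766). Chodl (ENSMUSG00000022860) lies on chromosome 16 at 78930948-78951733 and Nppc (ENSMUSG00000026241) on chromosome 1 at 86666291-86670571.

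Endothelial cells were too few after injury for a test of their genes, with 2 and 3 cells in the day 4 replicates and 0 and 14 in the day 7 replicates. In the 151 uninjured cells, Pecam1, an adhesion molecule of the vessel wall, was at 980 ± 315 CPM (SD, n = 2), Kdr, the main receptor of vascular endothelial growth factor, at 389 ± 30.8 and Plvap, a protein of endothelial pores, at 241 ± 16.6. The day 4 cells had 714 ± 59.2 CPM of Pecam1, 137 ± 95.2 of Kdr and 261 ± 23.3 of Plvap, from 66, 13 and 24 counts. The day 7 cells had 882, 313 and 201 CPM.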

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

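Of the tests below, the 2 on the unnamed cluster had their predictions written before their results were seen; the test of a difference between classes, and those on T or NK cells and on immediate early genes, were chosen after.

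The change from day 4 to day 7 differed between FAPs and monocytes or macrophages for 578 of 12768 genes (336 higher and 242 lower in FAPs, edgeR interaction term), and a difference between 2 groups of cells is what singled this result out. Among them, 13 genes passed the test in both classes in opposite directions. Tmem176a, a membrane protein gene, fell in FAPs (log2 change -2.29) and rose in monocytes or macrophages (2.21), a difference of -4.28 ± 0.31 (SE). Igf1 did the reverse (1.55 and -1.11, difference 2.83 ± 0.24), as did Ctsk, which encodes a protease (1.02 and -2.40). Hp fell in FAPs and rose in monocytes or macrophages (-1.37 and 1.52). For Il1b, Il1r2, Ccl9, Cd74 and H2-Aa, 76.2% to 100% of the counts in FAPs were expected from free RNA. In simulations this test recovered 62.5% of changes of 2 with 5.3% false calls, or 43% with 23.9% false calls when each gene kept its own spread, so the share of false calls among the 578 is uncertain. The sums of both classes came from the same pools and are not independent of each other.

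A cluster that received no class name held 125 of 5497 cells at day 4, 25 of 3034 at day 7 and 0 of 1359 in uninjured muscle, which allows up to 0.221%. It was singled out because the comparisons of genes do not use it. Acp5 and Ctsk, genes of bone-resorbing osteoclasts, led it and stood at 3501 ± 1038 and 2781 ± 68.4 CPM at day 4 (SD, n = 2). Doublets of 2 classes at their mean levels are argued against, because 6 of 7 listed osteoclast genes outside its leading genes exceeded their mean level in the highest named class, with a median ratio of 1.82. The cluster had median UMIs of 16618 and 30661.5 at day 4 against 6938 and 13461 in monocytes or macrophages, as doublets would also have. Doublets with cells far above a class mean are therefore not excluded for this cluster. An osteoclast or multinucleated giant cell program in macrophages may account for it and stays open: the lower replicate median over 9 genes was 0.789 above monocytes or macrophages on the log2 scale, short of the 1 predicted. Calcr and Siglec15 had no count in either and entered as 0, and the replicate medians over the other 7 genes, taken after this value was seen, were 3.73 and 1.60. Time after injury was not tested as a cause.

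T or NK cells rose to 45.0% of cells at day 7. Lymph node or blood carried into the preparations may be set against B cells per T or NK cell. These were at 0.0336 and 0.0394 in the day 7 replicates against 0.333 and 0.529 in uninjured ones, a ratio of 0.088. B cells thus did not rise along with T or NK cells, which a source with the uninjured mix would require. The ratio restates shares already known, and the mix of lymph node or blood was not measured. Carry-over from these is therefore not decided by it. A loss of FAPs that raised all other classes alike would leave no gap between the changes of those classes. The log2 change in share of dendritic cells minus that of B cells was 3.03 ± 0.84 (SE), so these shares did not move alike. This pair was picked with both changes known, does not include T or NK cells, and its SE takes the 2 changes as independent. The gap is therefore no separate test. The gap of tenocytes minus B cells, 2.85 ± 0.82, is weaker still, because the tenocyte change turned to -3.70, -1.24, -1.17 and -4.38 under 4 alternatives. Free RNA is argued against by its estimated share of at most 3.40% of their UMIs, a median over marker lists that ranged from 0.522% to 70.9% in day 7 replicate 2 and so a rough one. Lymphocytes entering the muscle by day 7, a difference in yield between preparations and a source poor in B cells stay open and were not tested.

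Immediate early and dissociation response genes were lower in FAPs at day 4 than in uninjured muscle. Free RNA in the uninjured droplets is argued against, at 5.4% of the list's UMIs, as is the depth of the sums, since the median log2 change was -1.50 with thinned sums. A dissociation response that differed between preparations may explain it: the list's median was below 0 in each of the 4 classes tested, the highest being -0.412. That value was of monocytes or macrophages with at least 10 cells, where the list did not pass (camera adjusted p = 0.312). In T or NK cells the call (camera adjusted p = 0.0475) ended without uninjured replicate 2, day 4 replicate 2 or day 7 replicate 1. Preparation and time after injury cannot be told apart here, because each preparation belongs to 1 group.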

How the results depend on the processing

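All alternatives to the tests of monocytes or macrophages with at least 10 cells, of myogenic cells, of T or NK cells, of tenocytes and of dendritic cells were chosen after the data were seen, as was leaving out the mixed cluster of low UMIs. The class sums of uninjured muscle were the smallest, from 15 and 17 monocytes or macrophages and 28 myogenic cells, which limited the added tests to 1836 and 423 genes. In fits without 1 replicate, the lone replicate of that group was assumed to vary like the other groups.

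The alternatives were compared with the main results for 38 class shares, 338 changes of named genes and 107 list tests. Each pair of a result and a setting was counted once, so a result is counted under several settings. Among settings other than leaving out a replicate, direction and call were kept in 266 pairs for class shares, 3562 for named genes and 160 for lists. The call ended for 26, 281 and 53, began for 5, 7 and 0, and the direction turned for 18, 5 and 1. The 53 pairs in which a list call ended were with an estimated correlation, except 3 under the block. With 1 replicate left out, direction and call were kept for 182, 1370 and 508, the call ended for 34, 439 and 26, began for 1, 4 and 14, and the direction turned for 11, 2 and 24. Except where a replicate was left out or too few genes were tested, the cause was not tested for any change given here.

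With the replicate number as a block, 5 classes changed at day 4 and 5 at day 7 against uninjured muscle. At day 4 the calls of B cells, Schwann or glial cells, differentiating myocytes and the unnamed cluster ended. At day 7 those of endothelial cells, Schwann or glial cells, differentiating myocytes, the cluster named myogenic progenitor and the unnamed cluster did. Between day 7 and day 4 the call of dendritic cells ended. Under the block, 463 genes changed in FAPs between day 7 and day 4, 330 and 42 in monocytes or macrophages with at least 10 cells at day 4 and day 7, and 59 in myogenic cells. Replicate numbers were shared between groups without a stated pairing. Differences between same-numbered replicates correlated across genes at -0.0263, 0.012 and -0.0762 in FAPs and at -0.0659 in monocytes or macrophages. The values largest in size were -0.299 in monocytes or macrophages with at least 10 cells (day 4 and day 7) and -0.158 in myogenic cells. The highest was 0.0596, in T or NK cells, so the numbers were not taken to pair the samples.

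The DESeq2 test gave 1090 changed genes in FAPs between day 7 and day 4, 680 in monocytes or macrophages in that comparison and 497 in those with at least 10 cells at day 7 against uninjured. No filter on low counts gave 1571, 1223 and 853 in these, 1504 in monocytes or macrophages at day 4 and 854 in myogenic cells. The filter of edgeR itself gave 857 in monocytes or macrophages at day 4 and 1309 in myogenic cells. The highest sublibrary count gave 626 in monocytes or macrophages between day 7 and day 4, and 289 at day 4 against uninjured. Thinned sums gave 355 in the latter and 110 in myogenic cells. In dendritic cells DESeq2 gave 196, no filter 540, the block 148, thinned sums 141, the mitochondrial limit of 10% 196 and doublets kept 121. In tenocytes DESeq2 gave 88, no filter 256, the block 209 and thinned sums 73. In T or NK cells at days 4 and 7 against uninjured, no filter gave 1014 and 953 and the highest sublibrary count 264 and 231, and thinned sums gave 229 at day 7. At least 1000 UMIs per cell gave 239 in monocytes or macrophages between day 7 and day 4, and doublets kept gave 446 in FAPs.

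Among non-immune classes alone, 4 classes changed at day 4, 4 at day 7 and 2 between them, and the log2 change in share turned for FAPs (0.195), myogenic progenitors (0.185) and tenocytes (0.718) at day 4 and for mature myofibers (0.880) at day 7. Tenocytes at day 7 against uninjured turned to -3.70 with at least 1000 UMIs per cell, -1.24 with doublets kept, -1.17 at Leiden resolution 2 and -4.38 without low sublibraries. Differentiating myocytes at day 7 turned to -0.536 with at least 1000 UMIs and -0.517 without low sublibraries. Neutrophils at day 4 turned to -0.0469 with TMM over classes, -0.290 with at least 1000 UMIs and -1.85 at Leiden resolution 2, and T or NK cells at day 4 to 0.0666 at Leiden resolution 2. FAPs between day 7 and day 4 turned to 0.0106 with TMM over classes, 0.285 with doublets kept and 0.272 without low sublibraries, and the unnamed cluster to 0.154 with doublets kept. Of single genes, Pdgfra in FAPs between day 7 and day 4 turned to 0.0773 and Ly6c2 in monocytes or macrophages at day 7 to -0.144 with the highest sublibrary count. Ccr2 at day 7 turned to 0.176 without a filter and 0.138 with edgeR's own, and Ifitm3 in T or NK cells at day 7 to -0.230 at Leiden resolution 2.

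Leaving out each replicate in turn gave 3 to 9 changed classes at day 7 against uninjured and 1 to 5 between day 7 and day 4. Changed genes in FAPs numbered 2868 to 4705 at day 4, 2256 to 2944 at day 7 and 154 to 955 between them. They numbered 281 to 1549 in monocytes or macrophages between day 7 and day 4, 107 to 731 at day 4 and 4 to 440 at day 7 in those with at least 10 cells, and 5 to 651 in myogenic cells. The log2 change in share spanned -0.635 to 0.973 for neutrophils and -0.777 to 0.399 for T or NK cells at day 4. At day 7 it spanned -0.801 to 0.194 for B cells, -0.753 to 0.276 for mature myofibers and -1.85 to 0.204 for neutrophils, and between the days -3.60 to 2.69 for endothelial cells and -1.97 to 0.0162 for neutrophils. Pdgfra in FAPs between the days spanned -0.354 to 0.0197 and Ccr2 at day 7 -0.549 to 0.216. Lists that turned had an adjusted p of 0.354 to 0.997 (ribosome biogenesis, FAPs at day 7). In monocytes or macrophages between the days it was 0.131 to 0.859 for glycolysis, 0.359 to 0.870 for p53 targets and 0.0917 to 0.650 for resident macrophages. At day 4 it was 0.025 to 0.936 for inflammatory cytokines and 0.0405 to 0.809 for MHC class II. In T or NK cells it was 0.58 to 0.974 for the cell cycle at day 4 and 0.165 to 0.968 for interferon response between the days. In tenocytes it was 0.0744 to 0.848 for the cell cycle, 0.227 to 0.857 for oxidative phosphorylation, 0.206 to 0.848 for immediate early genes and 0.487 to 0.857 for p53 targets, which also turned under the block (0.774). In dendritic cells it was 0.354 to 0.976 for extracellular matrix, 0.212 to 0.976 for p53 targets, 0.631 to 0.826 for glycolysis and 0.0705 to 0.976 for ribosome biogenesis.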

Other observations

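T or NK cells were tested for changed genes only after the data were seen. Cluster 4 held 85.1% of them in uninjured muscle, and cluster 1, led by genes of NK cells, held 14.9% in uninjured muscle, 51.9% at day 4 and 56.3% at day 7. The changes below can therefore lie in the make-up of the class. Ly6a, which encodes the surface protein Sca-1 of activated and memory T cells, had no count in uninjured T or NK cells and rose to 418 ± 18.3 CPM at day 4 (SD, n = 2; at least 8.74-fold, edgeR adjusted p = 0.000237) and to 363 ± 18.8 at day 7 (at least 7.59-fold). Lef1, a transcription factor of naive T cells (ENSMUSG00000027985, chromosome 3 at 131110471-131224356 in mm10), fell 20.9-fold at day 4 and 8.41-fold at day 7. S1pr1, the receptor by which lymphocytes leave tissues, fell 17.5-fold at day 4. Ifng, the gene of interferon gamma (ENSMUSG00000055170, chromosome 10 at 118441046-118445892), fell 4.08-fold from 664 ± 227 to 163 ± 0.609 CPM between day 4 and day 7 (adjusted p = 0.011), a call that ended without either day 4 replicate or either day 7 replicate. Of 1545 genes 466 changed at day 4 and 360 at day 7 against uninjured, and 43 between the days. Without 1 replicate these were 134 (day 4 replicate 2) to 735 (uninjured replicate 1), 109 (day 7 replicate 1) to 609 (uninjured replicate 1) and 0 (without day 4 replicate 1, day 4 replicate 2 or day 7 replicate 1, with 211, 154 and 92 genes at an unadjusted p under 0.05) to 391 (uninjured replicate 1). The last was 194 with DESeq2, 125 with the highest sublibrary count and 110 without a filter, but 24 with the mitochondrial limit of 10%, 22 with edgeR's own filter, 17 with at least 1000 UMIs or without low sublibraries, 10 with thinned sums and 6 under the block. Interferon response genes rose for 2 of 6 at day 4 (adjusted p = 0.0164; adjusted p = 0.217 with an estimated correlation) and at day 7 (adjusted p = 0.0184; adjusted p = 0.284 with an estimated correlation), calls that ended without uninjured replicate 1 (0.0514 and 0.0669). Glycolysis genes rose for 6 of 9 at day 4 (adjusted p = 0.00187; adjusted p = 0.198 with an estimated correlation) and fell for 2 of 9 between the days (adjusted p = 0.000358; adjusted p = 0.138 with an estimated correlation), and ribosome biogenesis genes then fell for 2 of 7 (adjusted p = 3.11e-05; adjusted p = 0.138 with an estimated correlation). At day 4 oxidative phosphorylation genes rose for 6 of 21 (adjusted p = 0.0437; adjusted p = 0.335 with an estimated correlation) and immediate early genes fell for 4 of 8 (adjusted p = 0.0475; adjusted p = 0.446 with an estimated correlation). Both of these calls ended without uninjured replicate 2 (0.157 and 0.142) or day 7 replicate 1 (0.0524 and 0.089), and the second also without day 4 replicate 2 (0.0788). Other lists did not pass, although ribosome biogenesis at day 4 passed without day 4 replicate 1 (0.0463).

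Tenocytes were also tested for genes after the data were seen, between day 7 and day 4. The day 4 replicates held 27 and 24 of them. Wisp2 fell 8.52-fold from 323 ± 4.55 to 37.5 ± 11.8 CPM (edgeR adjusted p = 0.0036), under each alternative run. The clusters that carried the name differed between clusterings, so these alternatives do not all test the same cells. Wisp2 also fell in FAPs between these days, where Tnc rose. Tnc rose 3.55-fold (adjusted p = 0.0107) and Prelp, which encodes a matrix proteoglycan, fell 4.42-fold (adjusted p = 0.00691), calls that ended without day 4 replicate 2. Of 3795 genes 42 changed, and 3 did without day 4 replicate 2, 16 without day 7 replicate 2 and 116 without day 4 replicate 1. Of 24 matrix genes 4 rose (adjusted p = 2.25e-07; adjusted p = 0.8 with an estimated correlation). No other list passed, although glycolysis and interferon response did without day 7 replicate 2 (adjusted p = 2.27e-06 and 0.0414).

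Dendritic cells were tested for genes between day 7 and day 4, also after the data were seen. Tnfrsf4, which encodes the costimulatory receptor OX40, rose 11.5-fold from 18.1 ± 1.53 to 209 ± 57.6 CPM (SD, n = 2; edgeR adjusted p = 0.00467), and Il2rb and Klra8, genes of NK cells, rose 12.8-fold and 32.7-fold (adjusted p = 0.0289 for both). Their log2 changes ranged from 2.91 (without day 4 replicate 2) to 5.07 (without day 4 replicate 1) for Il2rb and from 3.69 (without day 7 replicate 1) to 5.87 (without day 4 replicate 2) for Klra8. The class held 32 and 81 cells at day 7, when T or NK cells were 45.0% of all cells against 4.73% at day 4. T or NK cells among the cells of this class were not tested for. The rises of Tnfrsf4, Il2rb and Klra8 are therefore not shown to lie in dendritic cells. Plbd1 fell 1.9-fold from 739 ± 29.2 to 390 ± 6.92 CPM (adjusted p = 0.0289; the call ended with doublets kept). Clusters 9, 14, 22 and 25 held 64.7%, 24.8%, 7.27% and 3.26% of the class at day 4, and 43.4%, 26.5%, 15.9% and 14.2% at day 7. Of 5411 genes 72 changed (55 higher, 17 lower). The count was 182 without day 4 replicate 1, 214 without day 4 replicate 2, 379 without day 7 replicate 2 (188 higher, 191 lower) and 36 without low sublibraries, and without a filter 265 were higher and 275 lower. The lists of cell cycle (0 of 16 changed, adjusted p = 0.000689), immediate early (0 of 15, adjusted p = 0.0121) and interferon response genes (1 of 14 fell, adjusted p = 0.0131) were lower at day 7 (adjusted p = 0.812 with an estimated correlation for each), calls that ended without day 7 replicate 1 (0.0705, 0.2 and 0.0511). Oxidative phosphorylation (adjusted p = 0.0683) passed without day 7 replicate 2 (0.0265), and the other lists did not pass.

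Haemoglobin transcripts led the free RNA of both uninjured replicates, with Hbb-bs at 27190 and 49260 and Hba-a1 at 25100 and 40070 CPM. The cluster of cells with myofiber transcripts had a median mitochondrial share of 0%. The cluster named myogenic progenitor held 48 cells at day 4 of which 0 had a UMI of Chodl or Myod1 and 60.4% had a UMI of Dcn, a fibroblast gene.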
